A study of Pimephales promelas with 31 samples.

How the data were processed

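The measurements were 1-colour (Cy3) Agilent arrays of total RNA from adult male fathead minnow liver, extracted with Trizol per the labels. Per the file headers, each deposited scanner file held spot intensity extracted with Agilent Feature Extraction, in which the processed intensity was background subtracted and spatially detrended, and values near background were replaced by a surrogate. The authors' deposited series table held log2 values, loess normalised according to its name, with a lowest value of 2.7 that filled 29.2% of cells. Its 31 columns were mapped to fish by fish number, and each column correlated with its own array at 0.988 or more, closest among all 31. How that table was floored and centred is not given in the sources used here, and its column medians ran from 4.63 to 4.69. The array carried 61053 non-control spots for 49849 probes, of which 41517 had 1 spot, 7973 had 2 and 359 had 10.

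From the deposited intensity, log2 of the processed signal minus each array's 75th percentile was computed. The 1319 control spots and spots marked as outliers were left out, and spots of one probe were averaged on the log2 scale. No probe was saturated. A probe was kept when it was well above background on at least 75% of the arrays of at least 1 site, which left 25444 probes with 499 missing values. A bound ("at least N-fold") was given for a probe that was well above background on 0 arrays of a group. It set the mean of the brighter group against the mean of, per array, the higher of the lowest well-above-background signal and the probe's own.

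Samples were grouped by site from the titles, where the number in the title served as replicate number. Each sample was taken as the liver of a separate fish; the labels do not state this or the tanks used, so p-values measure only the spread between these samples. The deposited design text named a one-way analysis with false discovery control and PCFH as reference. limma 3.58.1 in R 4.3.3 was fitted to all 31 arrays with site as the only term, by lmFit and eBayes, and gave the moderated F test and each contrast. P-values were adjusted by Benjamini-Hochberg over probes, with a threshold of 0.05. The median between-fish SD was 0.60 on the log2 scale, and the number of arrays limits the precision. The procedure was tested on simulated data with 25444 probes, 100 changed 2-fold and 100 changed 4-fold. Noise was normal and independent between probes, so correlation between probes was left out. For NRWD against PCFH the procedure recovered 33% of 2-fold and 88% of 4-fold changes, with 10 unchanged probes called. It recovered 34% and 90% for NRWU against PCFH (7 unchanged called), and 31% and 83% for SFSR against PCFH (6). For NRWD against NRWU it recovered 32% and 84% (5).

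Probes sharing at least 25 bases in a row on either strand were counted as one sequence group. In 2838 pairs of probes with identical sequence, the log2 fold changes of NRWD against PCFH correlated at 0.971 across pairs, with a median absolute difference of 0.05. Slide was taken from the array barcode (5 slides) and scan day from the headers (2 days). For the shared reference, residuals of all arrays were shuffled among the groups in 100 draws, and the 8 PCFH fish were split 4 against 4 in all 70 ways for correlations and in 10 draws for shared calls. In the same 70 splits, probes called higher at NRWD alone against one set of 4 fish were read at NRWU and SFSR against the other set, a check added after seeing the data, as were the splits of NRWD and NRWU labels within slides.

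The files gave a gene name for 0 of the 49849 probes, and 0 probe IDs matched the gene table of the reference assembly. The gene lists and the test of estrogen marker levels fixed before the data were examined, and the rule for named genes that rested on gene names, were therefore not run. In their place, after the files had been seen, the 2 probes with the largest positive and the 2 with the largest negative log2 fold change past the threshold were named per contrast, using the brightest probe of each sequence group, together with, of the probes that passed at all 3 sites, the 2 higher and the 2 lower ones whose largest p over the sites was smallest. Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile and cyclic loess normalization, the deposited loess table, no filter on dim probes or only probes well above background on every array, slide as a fixed or random block, the plain one-way test, array weights, each fish left out, only the compared sites, and a fold threshold of 1.5. Array row as a block and leaving out both NRWU fish 52 and NRWD fish 70 were added after seeing the data. Another site in the design text has no samples analysed here.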

Results

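The series asked about endocrine disruption in fish exposed to water of the Shenandoah River watershed, and its liver arrays from 2014 were compared between sites. Liver RNA of 31 adult male fathead minnows (Pimephales promelas, a small cyprinid used in water testing) was hybridised to 1-colour arrays, with 1 array per fish. The reference site was Passage Creek at a fish hatchery (PCFH, n = 8). The other sites were the North River below a wastewater treatment plant (NRWD, n = 8), the North River above that plant (NRWU, n = 7) and the South Fork Shenandoah River at Bentonville (SFSR, n = 8). Between 17542 and 32350 of the 49849 probes per array were well above background, with a median of 26561, and the 75th percentile of intensity ran from 105 to 607. The median spot CV differed between sites (permutation test of ranks, two-sided, adjusted p = 0.0129 over 7 quality measures), from 10.8% ± 0.66 (SD, n = 8) at PCFH to 12.3% ± 0.91 (SD, n = 8) at SFSR, and the other 6 measures did not pass. Each of the 5 slides held fish of all 4 sites. All PCFH and NRWD fish lay in array row 2 and all SFSR fish in row 1. NRWU had 5 fish in row 1, all in array column 4, and 2 in row 2, in column 1. NRWD fish lay in array columns 1 to 3 and PCFH fish in columns 3 and 4. On each slide the NRWD fish lay in lower columns than the PCFH fish. The files do not pair probes with genes, so transcripts are given by probe ID and 60-base sequence, and their genomic positions were not analysed here.

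Across the 4 sites, 688 of 25444 tested probes differed, in 556 groups of probes with overlapping sequence. PCFH had the lowest site mean in 385 of them (56.0%) and the highest in 98. NRWD had the highest mean in 361, SFSR in 154 and NRWU in 75. The moderated F test of limma was used, with Benjamini-Hochberg adjustment at 0.05. With slide as a block 695 probes passed, 585 of them shared with the fit without it, and with array row as a block, an alternative chosen after seeing the data, 410 passed.

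The fish below the treatment plant differed most from the reference fish by number of probes. Against PCFH, 633 probes passed at NRWD, 482 higher and 151 lower. The lower count was 96 with quantile normalization, 86 with cyclic loess, 90 in the authors' deposited table of loess values and 53 with normexp background correction, where the higher counts were 387, 440, 384 and 407. The higher probes had a median fold of 2.77, and 32 of them were more than 8-fold higher. The lower probes had a median fold of 2.46, and 0 fell by more than 8-fold. CONTIG4883 (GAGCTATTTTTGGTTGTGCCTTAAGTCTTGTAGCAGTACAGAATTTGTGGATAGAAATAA) rose from -3.90 ± 1.396 (SD, n = 8) at PCFH to 2.12 ± 1.01 (SD, n = 8) at NRWD, a log2 fold change of 6.02 (SE 0.76, adjusted p = 1.51e-05). SINGLET_33342 (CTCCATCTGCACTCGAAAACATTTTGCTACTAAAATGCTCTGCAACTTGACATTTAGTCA) rose from -4.18 ± 1.03 to 1.81 ± 0.86 (SD, n = 8 each), a log2 fold change of 5.99 (SE 0.66, adjusted p = 1.06e-06). In PCFH these probes were well above background on 4 and 3 of the 8 arrays. SINGLET_2142 (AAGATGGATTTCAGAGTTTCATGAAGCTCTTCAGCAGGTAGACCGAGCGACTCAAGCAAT) fell from -0.56 ± 1.01 to -3.24 ± 0.95 (SD, n = 8 each), a log2 fold change of -2.68 (SE 0.53, adjusted p = 0.00322). UF_Ppr_AF_112122 (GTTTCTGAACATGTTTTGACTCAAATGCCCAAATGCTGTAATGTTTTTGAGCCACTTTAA) fell from -1.73 ± 1.68 to -4.36 ± 1.25 (SD, n = 8 each), a log2 fold change of -2.62 (SE 0.61, adjusted p = 0.0140), and was well above background on 3 of the 8 NRWD arrays. These 4 probes kept their direction within each of the 5 slides. With normexp background correction their log2 fold changes were 3.72, 3.44, -1.46 and -1.02. The call of UF_Ppr_AF_112122 was lost in 2 of 35 other settings, with an adjusted p of 0.0697 at most in limma. These were normexp and the authors' deposited table, 2 of the 4 settings that kept all fish. The remaining 31 settings left out 1 fish each. The 2 sites did not overlap in 170 probes, 152 higher and 18 lower at NRWD, where chance gives 0.0155% of probes, or 3.95. With slide as a block 653 probes passed, 551 of them shared. On scan day 1 (4 NRWD and 3 PCFH fish) 30 probes passed, and on scan day 2 (4 and 5 fish) 242 did.

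**Figure D1:**
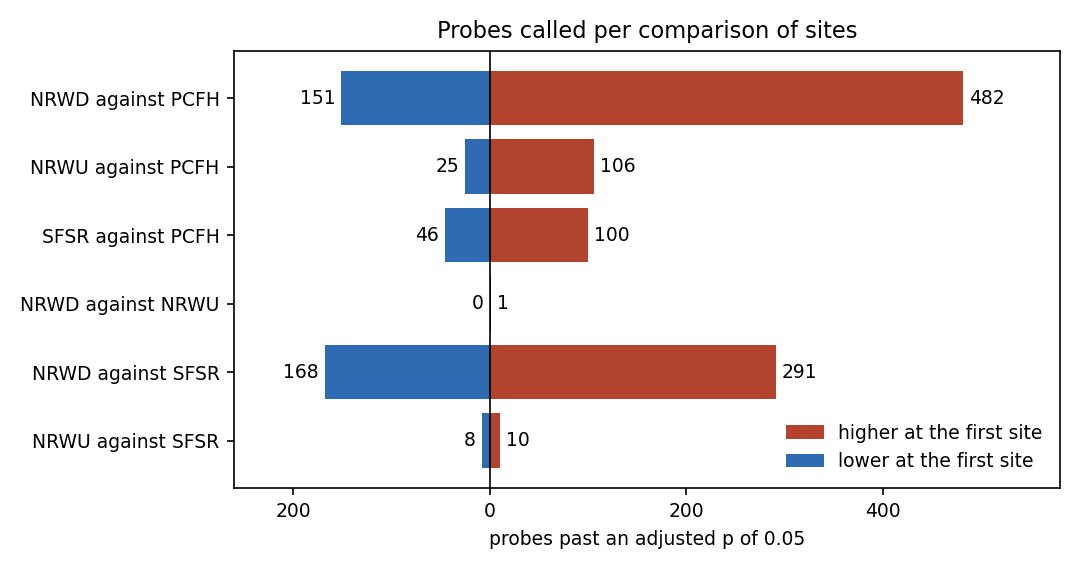
Number of probes past an adjusted p of 0.05 in each comparison of sites, higher to the right and lower to the left, from 31 arrays. NRWD against PCFH had 482 higher and 151 lower probes, and NRWD against NRWU had 1.

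Above the treatment plant, fewer probes passed against the reference. At NRWU 131 probes passed against PCFH, 106 higher and 25 lower, with median folds of 3.19 and 2.18. With normexp 61 were higher and 17 lower. SINGLET_12682 (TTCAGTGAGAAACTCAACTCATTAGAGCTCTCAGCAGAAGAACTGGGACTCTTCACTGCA) rose from -4.42 ± 1.48 (SD, n = 8) at PCFH, well above background on 3 of 8 arrays there, to -0.23 ± 0.91 (SD, n = 7) at NRWU, a log2 fold change of 4.18 (SE 0.51, adjusted p = 1.99e-05). CONTIG1792 (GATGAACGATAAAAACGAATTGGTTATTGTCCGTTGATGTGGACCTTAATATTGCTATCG) rose from -4.68 ± 0.93 (SD, n = 8) to -0.83 ± 0.47 (SD, n = 7), a log2 fold change of 3.85 (SE 0.32, adjusted p = 7.16e-09), and 1 of 8 PCFH arrays measured it well above background. With normexp background correction SINGLET_12682 was 1.82 higher on the log2 scale and CONTIG1792 was 1.55 higher. UF_Ppr_AF_112122 fell to -4.38 ± 1.04 (SD, n = 7), a log2 fold change of -2.64 (SE 0.64, adjusted p = 0.0490), a call that was lost in 25 of 35 other settings. It was well above background on 2 of 7 NRWU arrays, and its log2 fold change with normexp was -0.84 (adjusted p = 0.292 in limma). SINGLET_47539 (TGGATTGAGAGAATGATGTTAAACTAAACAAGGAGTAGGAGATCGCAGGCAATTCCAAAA) fell from -3.18 ± 1.09 (SD, n = 8) and was well above background on 0 of 7 NRWU arrays, so it was at least 2.62-fold lower there (adjusted p = 0.0218) under the background correction used. That call was lost in 4 of 35 other settings, with an adjusted p of 0.602 at most, and with normexp its log2 fold change was -0.47, short of that bound. The 2 sites did not overlap in 77 probes, where chance gives 7.91. The count was 97 with slide as a block, 43 without NRWU replicate 57 and 48 with array row as a block. The fit with row as a block set the PCFH fish against the 2 NRWU fish of row 2 alone. On scan day 1 (2 NRWU and 3 PCFH fish) 0 probes passed in limma, with 1209 at an unadjusted p under 0.05, and on scan day 2 (5 and 5 fish) 110 did.

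At the South Fork site, 146 probes passed against PCFH, 100 higher and 46 lower, with median folds of 2.59 and 2.08. The lower count was 83 with quantile normalization and 80 in the authors' deposited table, where 123 and 120 were higher. SINGLET_26057 (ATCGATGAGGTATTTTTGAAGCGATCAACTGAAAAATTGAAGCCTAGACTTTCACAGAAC) rose from -1.74 ± 0.33 at PCFH to 2.86 ± 0.80 at SFSR (SD, n = 8 each), a log2 fold change of 4.61 (SE 0.33, adjusted p = 9.53e-11). That log2 fold change was 3.65 with normexp background correction. CONTIG1792 rose to -0.35 ± 0.47 (SD, n = 8), a log2 fold change of 4.33 (SE 0.31, adjusted p = 9.53e-11), or 1.89 with normexp background correction. SINGLET_47539 was well above background on 0 of 8 SFSR arrays and at least 2.45-fold lower (adjusted p = 0.0477) under the background correction used, a call that was lost in 23 of 35 other settings. With normexp its log2 fold change was -0.49, short of that bound. SINGLET_11841 (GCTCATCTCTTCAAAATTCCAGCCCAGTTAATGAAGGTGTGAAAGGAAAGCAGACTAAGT) fell from -2.26 ± 0.39 (SD, n = 8) to -4.25 ± 1.02 (SD, n = 7), a log2 fold change of -1.99 (SE 0.42, adjusted p = 0.0172), with 1 of 7 SFSR arrays well above background. That call was lost in 3 of 35 other settings, with an adjusted p of 0.344 at most in limma. Among these were normexp and the authors' deposited table of loess values, 2 of the 4 settings that kept all fish. The log2 fold change was -0.52 with normexp and -1.35 in the deposited table. The 2 sites did not overlap in 76 probes, where chance gives 3.95. With slide as a block 161 probes passed, and 132 of them were shared. Array weights gave 158 higher and 115 lower probes, and leaving out the dim filter gave 74 and 18. On scan day 1 (3 and 3 fish) 11 probes passed and on scan day 2 (5 and 5 fish) 21 did. SFSR and PCFH fish shared no array row, and with row as a block 5 probes passed, while the median SE of this comparison went from 0.30 to 0.57. The median difference of the 146 probes, taken in their SFSR direction, was 1.298 on the log2 scale without that block and 1.34 with it. The row term rests on the NRWU fish alone.

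A set of probes changed against PCFH at all 3 sites: 25 were higher and 2 lower in each. UF_Ppr_AF_103842 (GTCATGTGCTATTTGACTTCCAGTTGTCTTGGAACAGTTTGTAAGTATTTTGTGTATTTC) was well above background on every array, at 1.05 ± 0.56 (SD, n = 8) in PCFH, 4.17 ± 0.44 (SD, n = 8) in NRWD, 4.49 ± 0.41 (SD, n = 7) in NRWU and 4.86 ± 0.42 (SD, n = 8) in SFSR. Its log2 fold changes were 3.11 (SE 0.23, adjusted p = 9.82e-10), 3.43 (SE 0.24, adjusted p = 1.83e-10) and 3.81 (SE 0.23, adjusted p = 4.50e-12). CONTIG1792 was 3.73 higher on the log2 scale at NRWD (SE 0.31, adjusted p = 6.60e-09), beside its rises at NRWU and SFSR, and 1.45 higher at NRWD with normexp. The probes past the threshold and lower at all 3 sites were SINGLET_47539 and SINGLET_29967 (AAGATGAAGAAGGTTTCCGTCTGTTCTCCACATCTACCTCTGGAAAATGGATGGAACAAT), and the latter had log2 fold changes of -0.85 (SE 0.23) at NRWD, -1.001 (SE 0.23) at NRWU and -1.09 (SE 0.23) at SFSR, with adjusted p of 0.0353, 0.0426 and 0.0142. With normexp these log2 fold changes were -0.49, -0.40 and -0.55. Its call was lost in 11 of 35 other settings at NRWD, in 15 at NRWU and in 0 at SFSR. The fit with slide as a block was among those that lost it at NRWU (adjusted p = 0.0639). SINGLET_47539 had a log2 fold change of -2.18 at NRWD (SE 0.50, adjusted p = 0.0123) and was well above background on 1 of 8 arrays there. With normexp that log2 fold change was -0.62 (adjusted p = 0.228), the only one of 35 other settings that lost this call, and the calls of SINGLET_47539 were lost at all 3 sites.

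**Figure D2:**
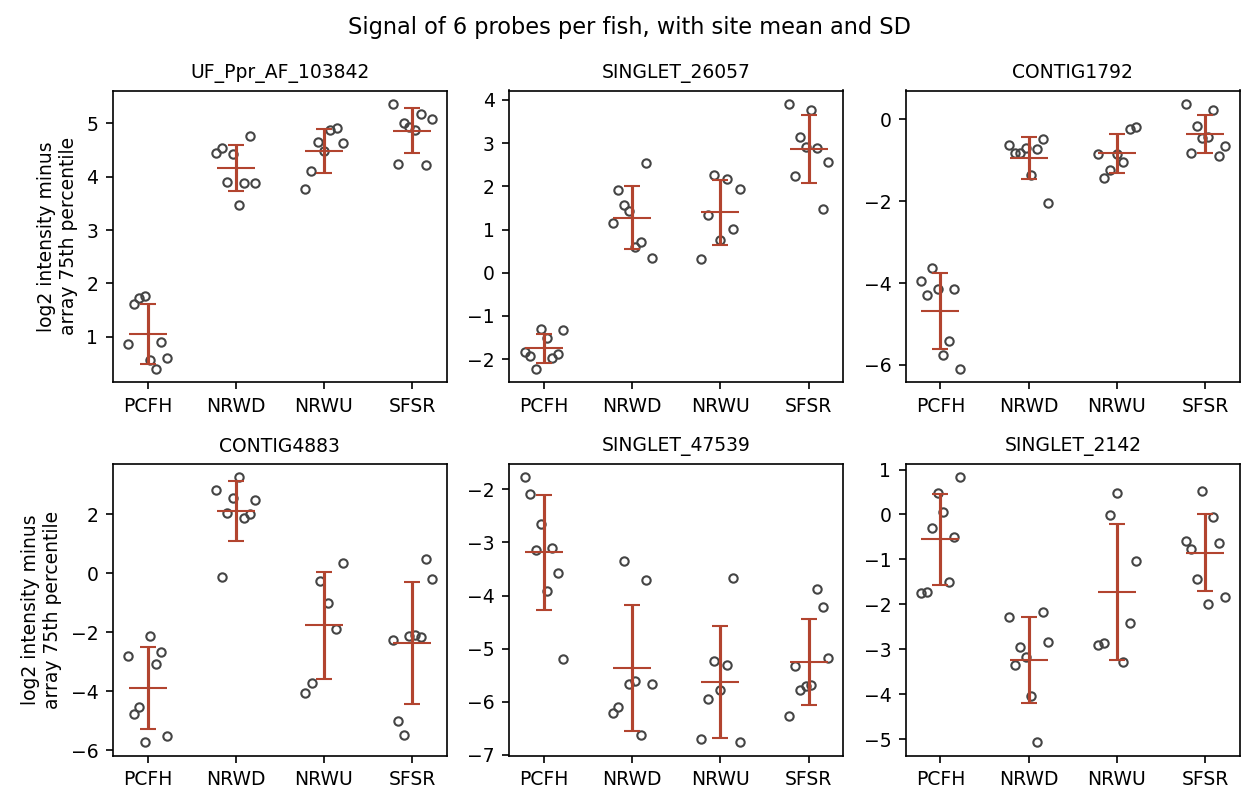
Log2 intensity minus the array's 75th percentile for 6 probes, with 1 open point per fish and the site mean and SD in red. UF_Ppr_AF_103842 lay between 0.40 and 1.76 in the PCFH fish and between 3.48 and 5.37 in all others.

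Probes that passed against PCFH at some sites and not at others were set beside their values at the remaining sites. Of the 383 probes higher at NRWD alone, 372 had the same sign at NRWU, with median log2 fold changes of 1.36 and 0.78, and 1 differed between NRWD and NRWU when that difference was tested. At SFSR 334 had the same sign, the median was 0.42, and 139 differed between NRWD and SFSR. Choosing probes past the threshold at NRWD and not at the other sites favours such differences. Each comparison was adjusted on its own, and NRWD and SFSR fish lay in different array rows. The signs and medians share the 8 PCFH fish, which alone raises the number with the same sign. In a check added after seeing the data, probes called higher at NRWD alone against 4 PCFH fish were read against the other 4, in 70 splits. Fewer probes pass against 4 reference fish, so some that passed at NRWU or SFSR against all 8 can be among those chosen. The check therefore does not describe the 383 probes themselves. A median of 95.002% of the chosen probes (87.2% to 99.2%) were higher at NRWU, by a median of 0.97 on the log2 scale, against 51.0% of all probes. At SFSR 81.5% were higher (71.3% to 91.6%), by a median of 0.44, against 50.4% of all probes. A further 62 probes were higher at both North River sites and not past the threshold at SFSR, with medians of 1.96, 1.68 and 0.82, and 28 of these differed between NRWD and SFSR. The 55 probes higher at SFSR alone had a median of 1.22 there, with 13 that differed between NRWD and SFSR and 3 between NRWU and SFSR. Of these probes 54 had the same sign at NRWD and 55 at NRWU, with medians of 0.61 and 0.75, again against the same PCFH fish. Over all probes, the log2 fold changes of NRWD and NRWU correlated at 0.63, those of NRWD and SFSR at 0.45 and those of NRWU and SFSR at 0.56 (across probes, which are not independent replicates). Unchanged groups simulated against a shared reference gave mean correlations of 0.47, 0.49 and 0.48, and at most 0.71, 0.70 and 0.68 over 100 draws. The covariances were 0.178, 0.122 and 0.134, against simulated means of 0.0830, 0.0818 and 0.0849 and highest values of 0.183, 0.147 and 0.175. Each observed correlation and covariance lay below the highest simulated one. With each site set against 4 different PCFH fish, the mean correlations were 0.29, 0.15 and 0.20. The 3 pairs shared 87, 37 and 33 higher probes and 6, 4 and 7 lower ones, where independent lists would share 2.01, 1.89 and 0.417 higher and 0.148, 0.273 and 0.0452 lower. With the PCFH fish split in this way, the median numbers of shared higher probes were 10.5, 11 and 7. In these 10 draws 0 lower probes were shared by any pair. Fewer probes pass against 4 reference fish, and few lower ones were shared to begin with. The draws therefore cannot tell whether shared lower probes depend on common PCFH fish.

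**Figure D3:**
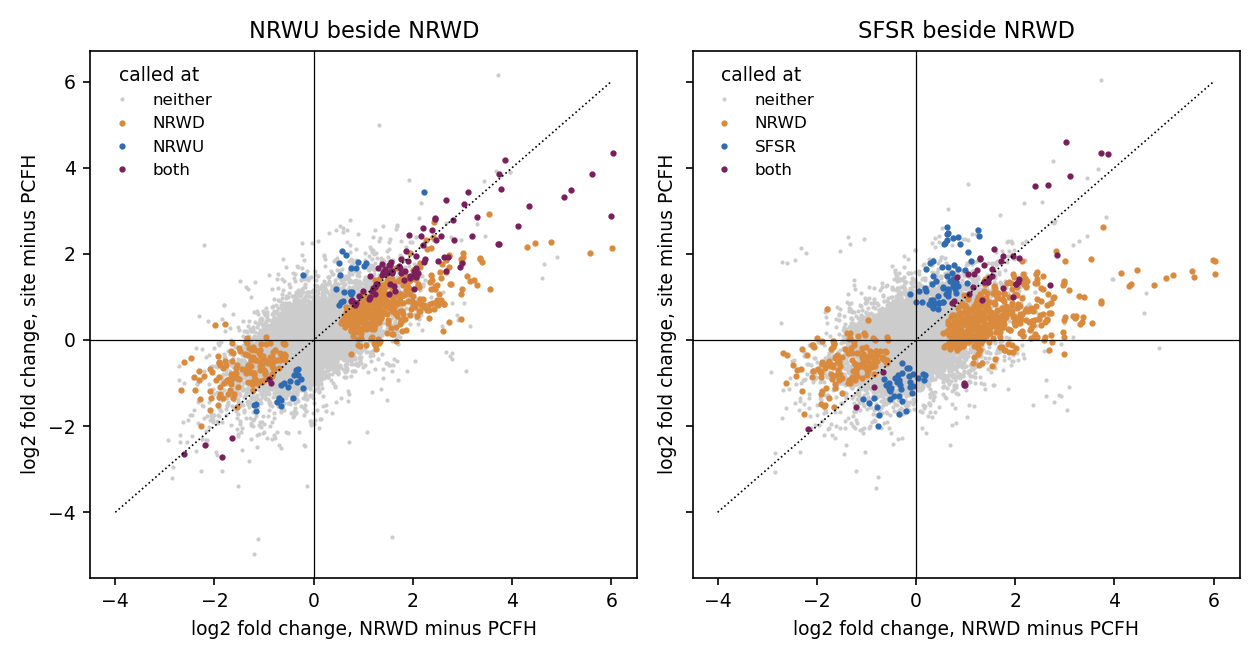
Log2 fold change against PCFH for each tested probe, NRWD on the horizontal axis and NRWU (left) or SFSR (right) on the vertical axis, coloured by where the probe passed an adjusted p of 0.05, with the line of equal change dotted. Correlations over all probes were 0.63 and 0.45.

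Below against above the treatment plant, 1 probe passed. UF_Ppr_AF_103232 (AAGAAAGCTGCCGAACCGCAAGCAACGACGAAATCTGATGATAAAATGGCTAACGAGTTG) was -2.72 ± 0.98 (SD, n = 8) at NRWD and -5.11 ± 0.82 (SD, n = 7) at NRWU, a log2 fold change of 2.39 (SE 0.40, adjusted p = 0.0310). It was well above background on 6 of 8 NRWD and 1 of 7 NRWU arrays, and was higher at NRWD within each of the 5 slides. Its call was lost in 8 of the 35 other settings that named probes were followed in, with an adjusted p of 0.607 at most there. In 5 further settings limma or the plain test called 0 probes in this comparison: without the dim filter, with only probes well above background on every array, with the plain test, with only the compared sites and with array row as a block. Its log2 fold change was 0.40 with normexp, which lost the call, and 2.19 to 2.42 in the 7 settings with a fish left out that lost it. In this comparison 2131 probes had an unadjusted p under 0.05, and 0 probes fell past the threshold. CONTIG4883 and SINGLET_33342 differed by 3.89 (SE 0.82) and 3.11 (SE 0.68) on the log2 scale with adjusted p of 0.106 and 0.117. With slide as a block 13 probes passed, among them CONTIG4883 (adjusted p = 0.0340) and SINGLET_33342 (adjusted p = 0.0488). Normexp gave 8 probes, 0 of them shared with the fit without it, and 12 passed when NRWU replicate 60 was left out. All 8 NRWD fish lay in array row 2 and 5 of 7 NRWU fish in row 1. Row as a block therefore set the NRWD fish against the 2 NRWU fish of row 2 alone. With row as a block 0 probes passed in limma and 967 had an unadjusted p under 0.05, as the median SE went from 0.31 to 0.47. UF_Ppr_AF_103232 then had a log2 fold change of 2.32 (SE 0.61, adjusted p = 0.754).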

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

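The tests of the percentile scaling, of the shared reference fish, of splits within slides and with row as a block were chosen after the result was seen, as were the comparisons of NRWD and NRWU with SFSR. The other tests below were fixed before it.

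Higher probes outnumbered lower ones at every site against PCFH. Under quantile and cyclic loess normalization the lowest share of higher calls was 59.7%, so the percentile scaling does not account for the excess, although the SFSR share moved from 68.5%. With each site set against different PCFH fish, pairs of sites still shared at least 5 higher probes, over independent-list medians of 0.0873, 0.234 and 0.0200. They shared 0 lower probes. Those shared higher calls thus did not need the same PCFH fish. Both fits took their spread largely from the same arrays, so independent lists are a loose yardstick. A deviation common to all PCFH fish would be in both fits, so the test cannot decide whether chance in these fish gives the excess. Whether the PCFH water, hatchery setting or other properties of that site set its fish apart was not tested and stays open.

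NRWD had 633 probes against PCFH and NRWU 131. Without any 1 NRWD fish the count was still at least 506, so no single fish carries it. In 40 splits, 500 probes were chosen in 4 NRWD and 4 PCFH fish. Over them the median NRWU difference was 64.7% of that in the held-out NRWD fish (48.6% to 86.7%). So the smaller NRWU difference over such probes was not only noise in the fish that chose them. All of them were chosen at NRWD, so these splits cannot tell whether that choice of site accounts for the gap in counts. The splits reuse the same fish, so a chance difference between these 8 and 7 fish may remain, and a graded site effect stays open, as the direct comparison had 1 probe, or 13 with slide as a block.

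SFSR and PCFH fish lay in different array rows. Over the 146 SFSR probes, the NRWU fish of row 1 differed from those of row 2 by a median of -0.066 log2 in the SFSR direction (SD 0.118 over the 21 choices of 2 fish), against a median SFSR difference of 1.298. The 5 NRWU fish of row 1 lay in array column 4 and the 2 of row 2 in column 1. An opposite effect of column could hide one of row, and only 2 NRWU fish lay in row 2. This difference therefore cannot decide whether array row is the source. With row as a block that SFSR median was 1.34, and 5 probes passed as the median SE rose from 0.30 to 0.57. That fit takes its row term from the same NRWU fish, so it is not a second test. NRWD and PCFH fish shared row 2, so row did not differ between those sites. Array column did differ: on each slide the NRWD fish lay in lower columns than the PCFH fish. Column was not tested as a source of their differences, and comparing within slides does not remove it.

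Other splits of the arrays were counted for each comparison. For the overall site test 1 of 100 splits, the real one, gave as many as 688 probes (highest other 8). The same held for 633 at NRWD (highest other 55), 131 at NRWU (highest other 39) and 146 at SFSR (highest other 19). A share of 1 in 100 is the lowest these splits can reach, so chance placing of single fish looks unlikely for these 4 counts. The splits treat fish as independent and the tanks are not known, so a chance difference between tanks is not excluded. For NRWD against NRWU without a block 10 of 100 splits gave at least 1 probe (highest other 3), so chance cannot be excluded for that count. With slide as a block and the labels exchanged within slides, 1 of 100 splits, the real one, gave as many as 13 probes (highest other 12). This test was added after the count of 13 had been seen, and that count was the highest of 14 other settings. The test therefore cannot exclude chance. Those settings ran from 0 to 13, and 5 of them gave 0. Row as a block was among these 5. Only NRWU had fish in rows 1 and 2, so that fit set the NRWD fish against the 2 NRWU fish of row 2 alone. So a difference between these sites that holds across settings was not shown.

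Compared directly, so that PCFH cancels, NRWD and SFSR differed in 459 probes, NRWU and SFSR in 18 and NRWD and NRWU in 1. The counts were 472, 9 and 13 with slide as a block. These probes did not have to pass against PCFH. Of 72 groups of values tested for a fish far from the rest, 7 had one, where chance gives 3.6. CONTIG4883 was -0.11 in NRWD fish 62, with the other NRWD fish at 1.89 to 3.26. SINGLET_33342 was -0.0873 in NRWD fish 70, with the others at 1.69 to 2.94. The 75th percentile of intensity was 607 in NRWD fish 67, against 323 at most in the others, and the SD of its negative controls was 5.06. That SD was 9.20 in SFSR fish 47. PCFH fish 74 had 21398 probes well above background, and NRWU fish 60 a median spot CV of 10.3%.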

How the results depend on the processing

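Array row as a block and leaving out both NRWU fish 52 and NRWD fish 70 were chosen after seeing the data. NRWD against PCFH stayed within 1.5 times its count in all 14 other settings (441 to 711) and with each fish left out (468 to 698). The overall test moved to 431 without the dim filter and 410 with row as a block (547 to 748 with each fish left out). NRWU against PCFH went to 78 with normexp, 48 without the dim filter, 212 with array weights, 67 with only the compared sites and 48 with row as a block. With each fish left out it ran from 43 to 165, and it was 82, 43 and 86 without NRWU replicates 55, 57 and 58 and 71, 62 and 79 without PCFH replicates 76, 77 and 78. SFSR against PCFH went to 92 without the dim filter, 273 with array weights and 5 with row as a block (106 to 185 with each fish left out). Its higher calls were 57.9% with array weights, 59.7% with quantile, 60.0% with the deposited loess table and 80.4% without the dim filter, against 68.5%. NRWD higher calls were 88.5% with normexp, against 76.1%. NRWD against NRWU gave 8 probes with normexp, 13 with slide as a fixed block, 2 without both doubted fish, and 0 without the dim filter, with only probes well above background on every array, with the plain test, with only the compared sites and with row as a block. With each fish left out it ran from 0 to 12 and moved in 15 of 31 cases, the highest without NRWU replicate 60. The correlations of contrasts moved to 0.29, 0.15 and 0.20 with the PCFH fish split 4 against 4. No named probe reversed with quantile, the deposited loess table, normexp, slide as a fixed block or a fish left out, the settings run for them; 77 of 651 values with a fish left out lost their call, and of 21 each, 8 did with normexp, 4 with the deposited table, 2 with quantile and 1 with slide as a block. Gene lists and estrogen marker levels could not be run under any setting, for want of gene names. The cause of these moves was not tested, except that row as a block raises the SE. Against NRWD or PCFH, that block leaves only the 2 NRWU fish of row 2. Probes near background limit the dim calls. No paired analysis was possible because the sites share no fish numbers.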

Other observations

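The 2 remaining pairs of sites were compared in the same fit, a choice made after the data were seen, and covariation in the SFSR and NRWD fish was read without a prediction fixed before. Between the site below the treatment plant and the South Fork, 459 probes differed, 291 higher and 168 lower at NRWD. Between NRWU and SFSR 18 did, 10 higher and 8 lower at NRWU. Slide as a block gave 286 higher and 186 lower for the first pair, and 4 higher and 5 lower for the other. CONTIG4883 was 4.48 higher on the log2 scale at NRWD than at SFSR (SE 0.76, adjusted p = 0.00174), and SINGLET_26057 was lower, with a log2 fold change of -1.58 (SE 0.33, adjusted p = 0.00891). NRWD and SFSR fish lay in different array rows, so row and site cannot be separated in that pair except through the NRWU fish. In those fish row went with array column. Against PCFH, 3 probes passed at 2 sites with opposite signs.

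The test of covariation among the PCFH fish was fixed before its result was seen. The hypothesis was that the probes higher at NRWD belong to transcripts that vary together from fish to fish. Over 356 of them (1 per sequence group), the mean pairwise correlation among the 8 PCFH fish was 0.0276, above 98.9% of 1000 random sets matched on signal but small in size. Among the 8 SFSR fish it was 0.200, above 100% of the sets, whose highest was 0.0167. Among the 8 NRWD fish it was 0.0710, above 100% of the sets, whose highest was 0.0157. The random sets were matched on signal alone and could mix directions, while the 356 probes were all chosen as higher at NRWD. That choice favours a higher correlation, so the comparison cannot decide the hypothesis. The mean of these probes relative to PCFH ran from 0.08 to 1.11 over the SFSR fish, 0.64 to 1.46 over the 7 NRWU fish and 1.42 to 1.86 over the NRWD fish, whose values chose the probes. Whether a shared response that differs in strength between fish, or a technical source common to these probes, underlies this was not tested.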
